A study of Mus musculus with 18 samples.

How the data were processed

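C57BL/6N mice aged 7 weeks received RECTAS at 100 mg/kg body weight in 0.5% carboxymethyl cellulose (CMC), or CMC alone, by mouth, in doses 4 h apart. Colon, lung and liver were taken 8 h after the initial dose. RNA was extracted with TRIzol, and polyadenylated RNA was made into libraries with the TruSeq stranded mRNA kit, per the labels' protocols. Each of the 6 groups (3 tissues, vehicle or RECTAS) held 3 libraries, 18 in all, and groups were taken from the labels. The labels do not state whether 1 animal gave all 3 tissues or what the replicate numbers mean.

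The authors deposited gene-level TPM for each library, and those values were used as deposited. HISAT2 2.2.0, RSEM 1.3.0 and the mouse build GRCm38 are named in the submitters' processing notes, without their roles or order. The annotation release and any filters are not given in the sources used here. Every column summed to the same total, so TPM keeps no read depth, and no interval or floor based on counts could be given. An increase of a few abundant genes lowers the TPM of all others, which is why scaling alternatives were run. The 20 highest genes held 30.4% to 32.5% of TPM in colon, 29.2% to 33.7% in lung and 35.4% to 37.5% in liver. Transcripts of the mitochondrial genome held 14.6% to 18.2% in colon, 8.09% to 9.6% in lung and 13.1% to 14.5% in liver. TPM of genes shorter than 300 nt is imprecise because few fragment positions exist, and Gm25791 and Gm44313 are such genes. Reads shared between near-identical genes, such as immunoglobulin segments, Hspa1a and Hspa1b, or a pseudogene and its parent, could have been divided in ways that cannot be seen here. No pair of libraries was identical (0), and the highest Pearson correlation between libraries was 0.995. Of the gene identifiers, 55141 matched GENCODE M21, which supplied GRCm38 coordinates and gene types, and 110 symbols occurred more than once.

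Within each tissue, genes with at least 1 TPM in at least 3 of 6 libraries were tested as log2(TPM + 1) with limma 3.58.1 (moderated test with a mean-variance trend, two-sided) in R 4.3.3. Adjustment was by Benjamini-Hochberg at 0.05. Gene lists with at least 5 kept members were tested with camera at a preset inter-gene correlation of 0.01. It compares the mean moderated t-statistic of members with that of other genes, so a few strong members can weigh. A list said to rank higher or lower is so by this comparison, as no test on ranks was used. Camera with an estimated correlation and fry, which asks whether members move 1 way on balance without comparing them with other genes, were run beside it. The 59 lists covered splicing, immune, xenobiotic, metabolic, stress, clock and proliferation genes, cell types of the 3 tissues and of tissues that could be carried over, liver zonation and sex bias, and the mitochondrial genome. Counts of list members past the threshold were taken over all genes and adjusted over the list alone. Differences between tissues were tested as interactions in 1 limma fit of all 18 libraries. The design, lists, alternatives and the rule for named genes were fixed before the data were examined.

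Named genes were, per tissue, up to 10 genes per direction past the threshold whose groups did not overlap, or, where no gene passed, the 5 per direction with the smallest unadjusted p. Up to 4 members with the smallest p were named per list that passed or held a called gene. Cftr, Clk1 to Clk4, Srsf6, the tissue markers, genes called in more than 1 tissue and the 5 leading genes per interaction were named too. Predicted genes and pseudogenes were named only where fewer than 5 others were available. Genes named from the average effect, from the count over all tissues, and the further splicing factor and liver genes in the closing section were chosen after their values were seen. Some genes measured under these rules are not reported here.

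Alternatives were pseudocounts of 0.1 and 5 TPM, no filter, a filter of 5 TPM, quantile normalisation, median ratio scaling, and rescaling without mitochondrial and the top 20 genes. Others were 1 fit of all 18 libraries, the replicate number as a block, array weights, robust variance, a threshold of 0.1 and leaving out each library. Added after seeing the data were the RECTAS effect averaged over the 3 tissues, the count of genes whose groups lay apart in the same direction in all 3 tissues (exact over 8000 relabelings within tissues), fits without genes under 300 nt, lung lists without genes over 10 times higher in liver, and the recount of Luc7l2 within its list without each library. Python 3.11.15 was used for annotation and figures.

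The limma procedure was tested on simulated data in which 200 genes were changed, all drawn from genes averaging above 5 TPM. Genes between 1 and 5 TPM were thus not covered. With 200 true changes the Benjamini-Hochberg cut is also easier to pass than where few genes change. The shares recovered are therefore not the power for the real comparisons. At a 2-fold change 65.5% of them were recovered in colon, 85% in lung and 84% in liver, and at 1.5-fold 20.5%, 47% and 24.5%. The averaged effect recovered 82% at 1.5-fold. A list raised 1.5-fold was recovered in each tissue with 0 other lists called. Noise was drawn independently for each gene, so this simulation cannot show list calls that arise from correlated genes. Exon-level and isoform-level measurements were not analysed here.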

Results

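Messenger RNA was profiled in colon, lung and liver of mice given RECTAS by mouth, a small molecule whose name stands for rectifier of aberrant splicing, or given the carboxymethyl cellulose vehicle alone. The series set out to evaluate changes in splicing. Values per gene can show changes in RNA abundance, including that of splicing factors, but not exon use. Each tissue had 3 vehicle and 3 RECTAS libraries, 18 in all, and expression was given per gene as TPM, a length-adjusted share of all transcripts. Between 23308 and 23874 genes lay above 0 in a colon library, 24084 to 25227 in a lung library and 19836 to 20502 in a liver library. TPM keeps no read depth, so the depth behind each value is unknown. The tissue labels were matched by marker genes: in vehicle libraries Alb (albumin) averaged 63655 TPM in liver, Sftpc (surfactant protein C) 30618 TPM in lung and Slc26a3 (an anion exchanger of colonocytes) 276 TPM in colon. The labels do not say that the 3 libraries of a group came from separate animals, so the p-values measure the spread between these samples. Means are given ± SD with n = 3 libraries per group, and log2 differences are RECTAS minus vehicle on the log2(TPM + 1) scale, which understates the change of low genes.

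In liver, Ddit4 (ENSMUSG00000020108, chromosome 10, 59949669 to 59951834, minus strand, GRCm38), a stress-induced inhibitor of mTORC1 signalling, rose 6.23-fold, from 3.54 ± 0.962 TPM under vehicle to 22.1 ± 2.24 TPM under RECTAS (log2 difference 2.36, SE 0.17). All 3 RECTAS libraries lay above all 3 vehicle libraries. Gm44313, annotated as a 138-nt miRNA gene (chromosome 11, 58954983 to 58955120, minus strand), was listed at 0 in each vehicle library and at 18.2, 21.2 and 11.1 TPM in the RECTAS libraries. These were the 2 of 11944 genes that changed by limma with Benjamini-Hochberg adjustment (adjusted p = 0.013 for Ddit4 and 0.00337 for Gm44313). Srxn1, which encodes sulfiredoxin, an antioxidant enzyme, was 2.03-fold higher at 32.9 ± 1.79 against 16.2 ± 2.16 TPM (adjusted p = 0.0674, and 0.0388 with libraries scaled by median ratios; range over its alternatives 0.00295 to 0.434). At an unadjusted p under 0.05, 1388 genes differed where 597 would by chance. In 2236 genes (18.7%) the groups did not overlap, where chance gives 10%. These chance values are averages, and correlated genes can move such counts far from them. Other splits of the libraries were not counted for them in any tissue. The Ddit4 call did not hold without vehicle library 3 (adjusted p = 0.0883) or without RECTAS library 1 (0.0788), 2 (0.173) or 3 (0.0926). It also ended with no filter (0.0778) and with the replicate number as a block (0.0814). Its range over the alternatives was 0.000425 to 0.173. The Gm44313 call ended in a fit of all 18 libraries (0.207) and with the replicate number as a block (0.0518), within a range of 0.000379 to 0.207. The count of changed genes was 6 without vehicle library 1, and 1 without vehicle library 3, RECTAS library 2 or RECTAS library 3. Of the genes under the unadjusted threshold 30.9% were higher, against 55.7% after median ratio scaling, 51.4% after quantile normalisation and 37.1% after rescaling without mitochondrial and the top 20 genes, where 8 genes passed, 6 higher and 2 lower.

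Stress and hormone response genes ranked high in liver under RECTAS. In the glucocorticoid response list, 20 of 27 measured members were higher, with a median log2 difference of 0.60. Tsc22d3 (GILZ, a mediator of glucocorticoid action) stood at 142 ± 17.8 against 45.6 ± 16.1 TPM, Cdkn1a (the cell cycle inhibitor p21) at 4.62 ± 0.576 against 1.88 ± 0.236 TPM, and Pck1 (a gluconeogenic enzyme) at 1599.8 ± 238 against 898 ± 95.1 TPM. Adjusted over the list alone, 10 members rose, and over all genes tested 1 did (Ddit4). The list ranked above other genes by camera (adjusted p = 2.31e-10; adjusted p = 0.127 with an estimated correlation), and by fry its members moved up on balance (adjusted p = 0.0346). NRF2 targets, the antioxidant and conjugation genes, were higher in 24 of 30 members (median 0.25), among them Ephx1 (epoxide hydrolase) at 253 ± 19.1 against 155 ± 10.5 TPM and Gstp1 (a glutathione transferase) at 706 ± 71.3 against 436 ± 46.3 TPM. Adjusted over the list alone 9 NRF2 targets rose, over all genes none did (0), and the list gave an adjusted p of 1.34e-11 by camera (adjusted p = 0.427 with an estimated correlation). Heat shock genes were higher in 20 of 22 members (median 0.32), with the chaperone gene Hspa8 at 831 ± 132 against 598 ± 118 TPM. No heat shock member passed over the list alone (0), and the list gave an adjusted p of 2.91e-08 (0.711 as adjusted p with an estimated correlation); without vehicle library 1 its median was 0.17. Targets of ATF4, the transcription factor of the integrated stress response, were higher in 19 of 24 members (adjusted p = 3.99e-06; adjusted p = 0.711 with an estimated correlation), with Ddit4 the 1 member past the threshold over the list alone.

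**Figure D1:**
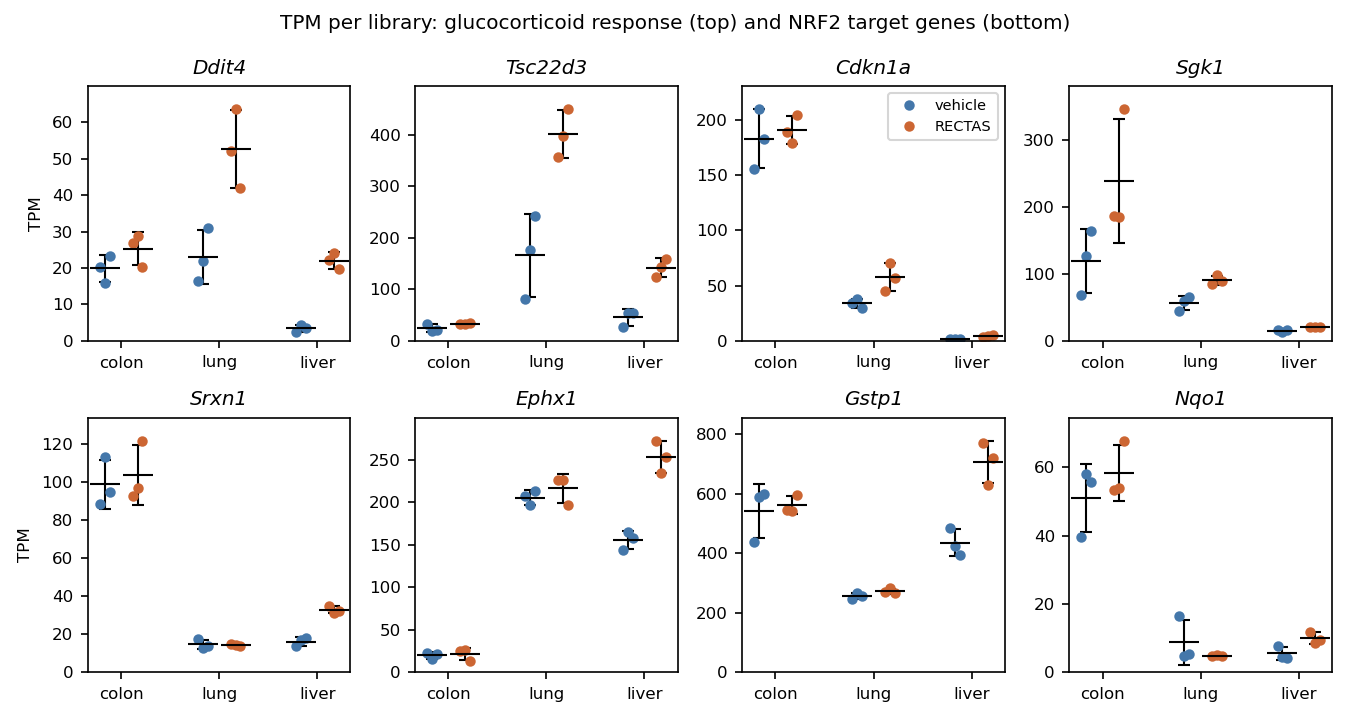
TPM of Ddit4, Tsc22d3, Cdkn1a, Sgk1, Srxn1, Ephx1, Gstp1 and Nqo1 in each library (points) of colon, lung and liver, with the mean and SD of the 3 libraries per group. In liver, Ddit4 averaged 3.54 TPM under vehicle and 22.1 TPM under RECTAS.

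Genes of drug and lipid metabolism were also higher in liver. Among targets of the xenobiotic receptors CAR and PXR, 23 of 34 were higher, including Ugt2b35 (a glucuronosyltransferase) at 99.1 ± 8.12 against 55.4 ± 11.8 TPM and Ces2c (a carboxylesterase) at 20.3 ± 2.45 against 9.41 ± 3.38 TPM. Over the list alone 4 CAR and PXR targets rose and 1 fell, with 0 over all genes (camera adjusted p = 8.1e-05; adjusted p = 0.711 with an estimated correlation). Their median was 0.20. It was 0.084 without vehicle library 1, 0.13 without RECTAS library 3 and 0.30 without vehicle library 2, and the call held each time. Cholesterol synthesis genes were higher in 23 of 26 members (median 0.32), with Insig1 at 279 ± 76.2 against 183 ± 8.77 TPM. None of the 26 passed over the list alone (0), and the list gave an adjusted p of 4.82e-08 (adjusted p = 0.802 with an estimated correlation; median 0.10 without vehicle library 1). The club cell list ranked high through 5 members that liver also expresses, led by the xenobiotic enzyme gene Cyp2a5 at 855 ± 252 against 446 ± 79.5 TPM (adjusted p = 0.00135; adjusted p = 0.427 with an estimated correlation). PPARA targets were higher in 31 of 39 members, with Angptl4 (a lipoprotein lipase inhibitor) at 53.7 ± 0.63 against 18.5 ± 7.36 TPM. Another member, Txnip, was lower, at 37.3 ± 6.92 against 74.8 ± 4.23 TPM. The PPARA list gave an adjusted p of 0.000161 by camera (adjusted p = 0.86 with an estimated correlation). Without vehicle library 1 its adjusted p was 0.0818 and its median −0.05. Pericentral hepatocyte genes, with Cyp1a2 at 424 ± 37 against 301 ± 27.3 TPM, passed at an adjusted p of 0.00189 (adjusted p = 0.803 with an estimated correlation; 0.13 without vehicle library 1). The AhR target, unfolded protein response, cell cycle and fatty acid synthesis lists passed at adjusted p = 0.0244, 0.0311, 0.0331 and 0.0374 (adjusted p = 0.711, 0.91, 0.86 and 0.91 with an estimated correlation). Leaving out 1 library ended these calls. The AhR call was lost without vehicle 2 (0.0642), RECTAS 1 (0.0934) or RECTAS 3 (0.068), and the unfolded protein call without vehicle 1 (0.475, median −0.060), RECTAS 1 (0.051) or RECTAS 2 (0.852). The cell cycle call was lost without vehicle 2 (0.0621), vehicle 3 (0.192) or RECTAS 3 (0.767, median −0.024) and after median ratio scaling (0.108). The fatty acid call was lost after median ratio scaling (0.0946) and without vehicle 1 (0.892, direction turned), RECTAS 1 (0.0533) or RECTAS 3 (0.338).

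Interferon-stimulated genes were lower in liver. In the type I interferon list 25 of 28 members were lower (median −0.31), with Usp18 at 10.7 ± 1.35 against 17.1 ± 2.39 TPM and Ifih1 (the RNA sensor MDA5) at 11.4 ± 0.268 against 14.4 ± 0.307 TPM. None passed over the list alone (0), and the list gave an adjusted p of 5.94e-05 by camera (adjusted p = 0.803 with an estimated correlation; median −0.20 without vehicle library 1). Sinusoidal endothelial markers were lower in 13 of 14 members, with Kdr (VEGF receptor 2) at 6.94 ± 1.09 against 9.63 ± 1.33 TPM (adjusted p = 0.00982; adjusted p = 0.803 with an estimated correlation). Interferon gamma genes were lower in 16 of 17 members (adjusted p = 0.0328; adjusted p = 0.91 with an estimated correlation). Male-biased liver genes were lower in 13 of 16 members, with Cyp2d9 at 32.9 ± 6.66 against 71.8 ± 31.2 TPM (adjusted p = 0.0407; adjusted p = 0.803 with an estimated correlation). These calls ended without single libraries: sinusoidal markers without vehicle 3 (0.116) or RECTAS 1 (0.1001), interferon gamma genes without vehicle 1 (0.65), RECTAS 1 (0.282) or RECTAS 2 (0.231), and male-biased genes without vehicle 3 (0.679), RECTAS 1 (0.116) or RECTAS 3 (0.112). In all 17 of 47 lists passed in liver, 13 higher and 4 lower, and 11 higher and 6 lower after median ratio scaling. With an estimated correlation 0 passed, and by fry 1 did.

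In lung, immediate early and glucocorticoid response genes were the most raised groups among those that passed. Ccn2 (connective tissue growth factor) averaged 149.8 ± 10.7 against 75.3 ± 6.82 TPM, Rhob (a small GTPase) 214 ± 11.1 against 109.8 ± 22.1 TPM and Jund (an AP-1 subunit) 148 ± 3.95 against 118 ± 1.58 TPM. Among immediate early genes 21 of 29 were higher, 11 rose adjusted over the list alone and 0 over all genes (camera adjusted p = 0.00325; adjusted p = 0.786 with an estimated correlation; 0.0504 without RECTAS library 3). The immediate early median was 0.32, and 0.19 without vehicle library 3. Glucocorticoid response genes were higher in 23 of 27 members (median 0.50), with Map3k6 at 26.9 ± 3.44 against 13.7 ± 2.43 TPM, Nfkbia (the NF-kB inhibitor) at 229 ± 25.7 against 136 ± 20.2 TPM and Ddit4 at 52.6 ± 10.8 against 23.1 ± 7.33 TPM. Over the list alone 15 rose and over all genes 0 (adjusted p = 3.17e-07; adjusted p = 0.786 with an estimated correlation). Over all lung genes tested the median log2 difference was 0.058, and 0.0019 after median ratio scaling. Targets of p53 had a median of 0.12, and 0.060 after that scaling. They were higher in 24 of 27 members, with Sesn2 at 11.7 ± 0.326 against 7.37 ± 1.13 TPM and Fas at 62.6 ± 5.17 against 46.6 ± 3.52 TPM. Of these 5 rose over the list alone and 0 over all genes (adjusted p = 0.000856; adjusted p = 0.786 with an estimated correlation). Heat shock genes were higher in 21 of 23 members, with the inducible chaperone gene Hspa1a at 8.16 ± 1.37 against 4.29 ± 0.945 TPM. Of these 2 rose over the list alone (adjusted p = 0.000454; adjusted p = 0.786 with an estimated correlation; 0.0624 without RECTAS library 3).

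The 1 of 15699 lung genes that changed by limma was Gm25791, annotated as a 137-nt snoRNA gene (chromosome 9, 15314845 to 15314981, plus strand), listed at 0 in each vehicle library and at 13.4, 22.4 and 20.7 TPM under RECTAS (adjusted p = 0.00148). Ccn2 had an adjusted p of 0.0851 (0.0276 to 0.469 over its alternatives). The Gm25791 call ended in a fit of all 18 libraries (0.111; range 0.000408 to 0.111), where 33 other lung genes passed. At an unadjusted p under 0.05, 1977 genes differed where 785 would by chance. In 3035 genes (19.3%) the groups did not overlap, where chance gives 10%. As in liver, these chance values are averages given without their spread. Of the 1977, 85.1% were higher, against 56.3%, 55.9% and 54.7% after median ratio scaling, quantile normalisation and rescaling without mitochondrial and the top 20 genes. Without vehicle library 1 or without RECTAS library 3 the count of changed genes was 2.

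Alveolar genes were higher and ciliated cell genes lower in lung under RECTAS. All 16 alveolar type 2 markers were higher (median 0.22), including the surfactant protein genes Sftpa1 at 3955 ± 132 against 3281 ± 208 TPM and Sftpd at 899 ± 39.6 against 761 ± 41 TPM (adjusted p = 0.000545; adjusted p = 0.786 with an estimated correlation). Alveolar type 1 markers were higher in 11 of 12, with Lmo7 at 263 ± 11.2 against 215 ± 9.65 TPM and 2 members that rose over the list alone (adjusted p = 0.00673; adjusted p = 0.786 with an estimated correlation). All 16 ciliated cell markers were lower (median −0.21), with Cfap126 at 50.6 ± 6.75 against 62.9 ± 6.95 TPM (adjusted p = 1.36e-07; adjusted p = 0.786 with an estimated correlation). Their median was −0.10 without vehicle 3, −0.33 without RECTAS 2 and −0.14 without RECTAS 3. Club cell markers had a median of −0.05 but a mean of 0.45, so median and mean differed in sign. Their median was −0.12 without vehicle 2, −0.082 without RECTAS 2, 0.0165 without vehicle 1 and −0.11 after median ratio scaling. Cckar, a cholecystokinin receptor gene, fell over the list alone, at 51.4 ± 2.16 against 65.2 ± 2 TPM (adjusted p = 0.0199; adjusted p = 0.786 with an estimated correlation). Endothelial markers were higher in 15 of 16, with Esam at 275 ± 13.7 against 242 ± 18 TPM (adjusted p = 0.0243; adjusted p = 0.791 with an estimated correlation). Leaving out 1 library ended the type 1 call (vehicle 3, 0.0601; RECTAS 3, 0.116), the club cell call (vehicle 3, 0.783, median 0.097; RECTAS 3, 0.218, median 0.050) and the endothelial call (vehicle 3, 0.18; RECTAS 2, 0.263), and median ratio scaling ended the club cell call (0.123). After median ratio scaling the type 1 median went from 0.14 to 0.078 and the endothelial median from 0.16 to 0.094. Vehicle library 3 held the most hepatocyte RNA of the 6 lung libraries, with Alb at 782 TPM.

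Interferon genes were lower in lung as well: 25 of 29 type I interferon genes (median −0.20), with Isg15 at 29.9 ± 5.98 against 43.4 ± 8.6 TPM, and 16 of 18 interferon gamma genes (median −0.24), with the guanylate-binding protein gene Gbp3 at 30.8 ± 3.41 against 39.8 ± 5.14 TPM. The lists gave adjusted p = 1.37e-08 and 2.59e-07 (adjusted p = 0.786 with an estimated correlation for both), and none of their members passed over the list alone (0 in each). Without vehicle library 1 the medians were −0.12 and −0.094, and without vehicle library 3 the interferon gamma median was −0.36. NRF2 targets were lower in 19 of 30 members, with Gstm4 at 7.94 ± 0.473 against 9.92 ± 0.819 TPM (adjusted p = 0.00242; adjusted p = 0.786 with an estimated correlation; 0.301 without vehicle library 1). Transcripts of the mitochondrial genome were lower in 10 of 13, with mt-Nd1 at 6236 ± 684 against 7087 ± 437 TPM (adjusted p = 0.000856; adjusted p = 0.786 with an estimated correlation; 0.142 without RECTAS library 2). Genes for hnRNP proteins, which bind pre-mRNA, were higher in 25 of 26, with Pcbp1 at 138 ± 3.38 against 123 ± 2.58 TPM (adjusted p = 0.0243; adjusted p = 0.786 with an estimated correlation). That call ended after median ratio scaling (0.269) and without vehicle 1 (0.0692), vehicle 3 (0.138), RECTAS 1 (0.109) or RECTAS 3 (0.218), within a range of 0.00177 to 0.786 over its alternatives. B and plasma cell, erythroid and cell cycle lists ranked lower (adjusted p = 0.00826, 0.0177 and 0.0199; adjusted p = 0.786, 0.786 and 0.828 with an estimated correlation). Their calls ended without vehicle 1 (0.345, 0.249 and 0.223), the B and plasma cell call also without RECTAS 3 (0.127), the erythroid call without vehicle 2 (0.0747) or RECTAS 1 (0.6003), and the cell cycle call without vehicle 2 (0.0623), RECTAS 2 (0.463) or RECTAS 1 (0.992, direction turned). The median turned positive for B and plasma cell markers without vehicle 1 (0.0086), for erythroid markers without RECTAS 1 (0.013) and for the cell cycle without each of its 4 libraries (0.0035 to 0.11). Erythroid and cell cycle calls also ended after median ratio scaling (0.0649 and 0.123).

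**Figure D2:**
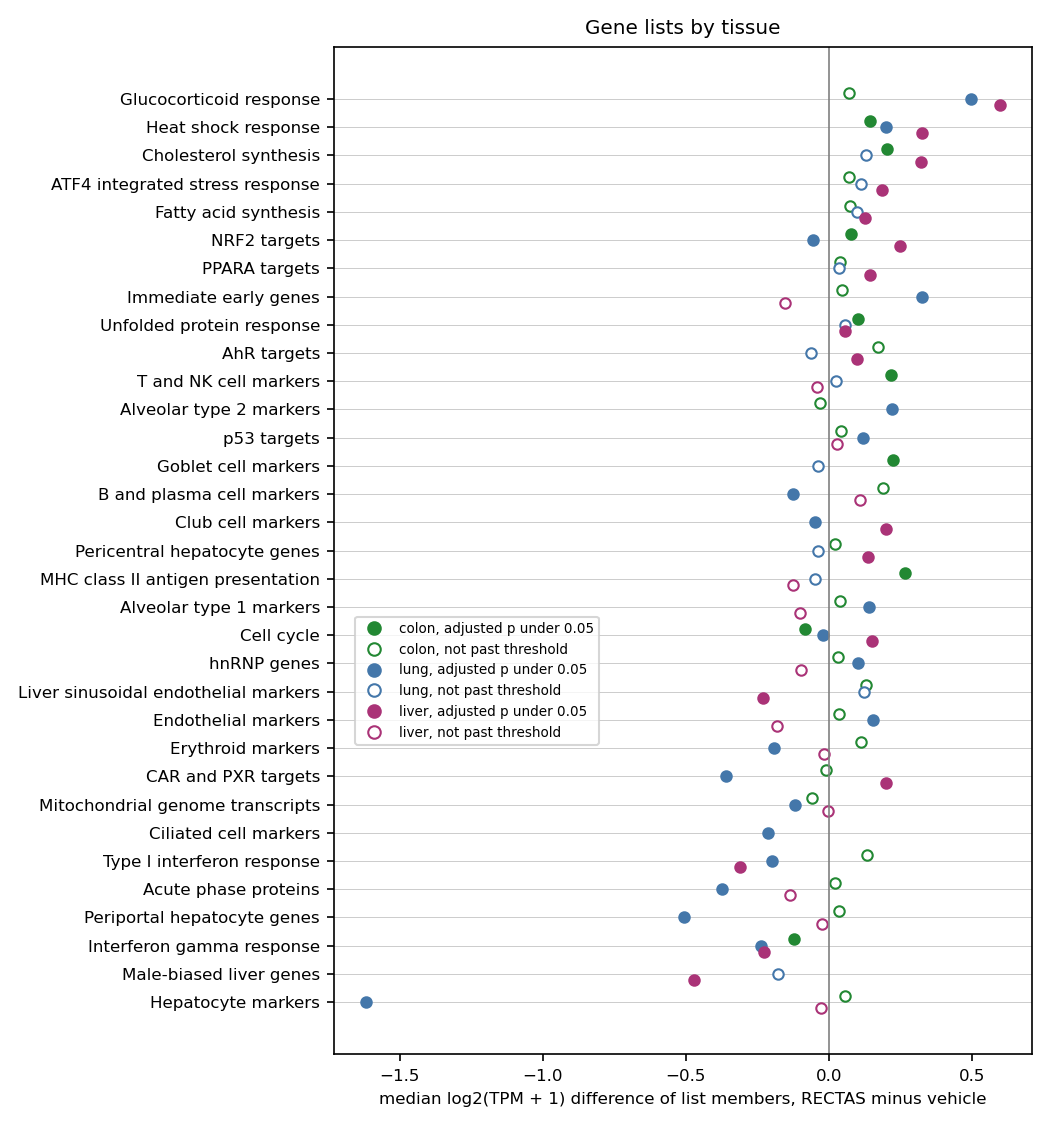
Median log2 difference (RECTAS minus vehicle, log2(TPM + 1) scale) of gene lists in colon, lung and liver, with filled points for lists past the threshold by camera with the preset correlation. Glucocorticoid response genes had medians of 0.60 in liver and 0.50 in lung.

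Hepatocyte genes were detected in lung and were lower under RECTAS. Alb stood at 9.07, 292 and 782 TPM in the vehicle libraries and at 0.81, 28.5 and 334 TPM in the RECTAS libraries, so the groups overlapped. Ahsg (fetuin-A) averaged 26.6 ± 37.5 against 108 ± 120.2 TPM. The hepatocyte list was lower in 19 of 20 members (median −1.62), at an adjusted p of 9.36e-06 (adjusted p = 0.786 with an estimated correlation) and at 0.0625 with a median of −0.53 without vehicle library 3. Its median was −0.52 without RECTAS 1, −3.02 without vehicle 1 and −2.82 without RECTAS 3. Acute phase, periportal and CAR and PXR lists, which hold liver genes, followed it at adjusted p = 0.00308, 0.00341 and 0.00459 (adjusted p = 0.786 with an estimated correlation for each). Vehicle library 3 decided these too (0.468, 0.605 and 0.465 without it); the periportal and CAR and PXR calls also ended without RECTAS library 1 (0.12 and 0.0521) or 2 (0.0804 and 0.0676). With genes over 10 times higher in vehicle liver than in lung left out, a choice made after seeing the data, the acute phase and CAR and PXR lists no longer passed (adjusted p = 0.263 and 0.422), and the CAR and PXR median was 0.0042. Cyp2b10, a CAR target that lung expresses highly, averaged 239 ± 9.16 against 201 ± 5.62 TPM. In all 21 of 55 lists passed in lung, 8 higher and 13 lower. With an estimated correlation 0 did, and by fry 2 did, both outside the 21: ATF4 targets (22 of 32 higher, adjusted p = 0.0489) and the sinusoidal endothelial list (10 of 10 higher, adjusted p = 0.0489).

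**Figure D3:**
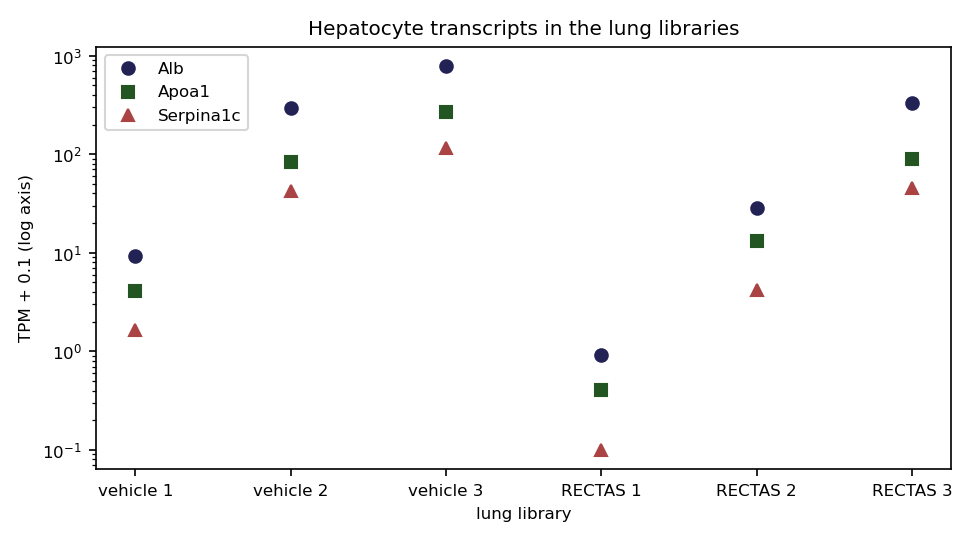
TPM + 0.1 (log axis) of the hepatocyte genes Alb, Apoa1 and Serpina1c in each of the 6 lung libraries, 3 vehicle and 3 RECTAS. Alb spans 0.81 TPM in RECTAS library 1 to 782 TPM in vehicle library 3, and the groups overlap.

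In colon, heat shock genes were higher under RECTAS in 21 of 23 members (median 0.14), with Hspa8 at 749 ± 59.2 against 629.6 ± 24.7 TPM and the co-chaperone gene Fkbp4 at 135 ± 8.48 against 118 ± 8.66 TPM. The list gave an adjusted p of 3.33e-08 by camera (adjusted p = 0.944 with an estimated correlation; median 0.23 without RECTAS library 2), and none of its members passed over the list alone (0). Cholesterol synthesis genes were higher in 24 of 26 members, with Lss (lanosterol synthase) at 24.4 ± 4.32 against 18.5 ± 4.12 TPM (adjusted p = 8.6e-06; adjusted p = 0.944 with an estimated correlation). Unfolded protein response genes were higher in 20 of 21 members, with the chaperone gene Hyou1 at 23.5 ± 2.09 against 20.3 ± 1.96 TPM (adjusted p = 0.000458; adjusted p = 0.944 with an estimated correlation). Of 10 T and NK cell markers 9 were higher and Gzma (granzyme A) rose over the list alone, at 2.32 ± 0.964 against 0.55 ± 0.242 TPM (adjusted p = 0.000983; adjusted p = 0.944 with an estimated correlation). The cholesterol call ended without vehicle 1 (0.0966) or RECTAS 1 (0.247), the unfolded protein call without RECTAS 1 (0.217) and the T and NK call without vehicle 1 (0.312) or RECTAS 3 (0.315).

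MHC class II, NRF2 and goblet cell lists were also higher in colon, and interferon gamma and cell cycle lists lower. H2-DMb1, a class II peptide-loading gene, averaged 3.24 ± 0.463 against 2.58 ± 0.172 TPM, Txnrd1 (thioredoxin reductase) 132 ± 5.55 against 114 ± 6.04 TPM and Clca1, secreted by goblet cells, 1331 ± 704 against 892 ± 264 TPM. Iigp1, an interferon-inducible GTPase, averaged 1.52 ± 0.492 against 3.17 ± 2.53 TPM. In order the lists gave adjusted p = 0.00973, 0.0137, 0.0215, 0.00141 and 0.0431 by camera (adjusted p = 0.944 with an estimated correlation for each), and none of their members passed over the list alone (0 in each). Single libraries decided all 5. The class II call ended without vehicle 1 (0.344), RECTAS 2 (0.2198) or RECTAS 3 (0.353). Without vehicle 1 (0.458) or RECTAS 3 (0.905) the NRF2 call ended and its camera direction turned. The goblet call ended without vehicle 2 (0.284), RECTAS 1 (0.457) or RECTAS 3 (0.378). The interferon gamma call ended without vehicle 2 (0.322, direction turned) or RECTAS 1 (0.111), and the cell cycle call without vehicle 2 (0.409), RECTAS 2 (0.7903) or RECTAS 3 (0.315, direction turned). The NRF2 call also ended after median ratio scaling (0.0698).

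No colon gene changed by limma: 0 of 14282 passed, and the lowest adjusted p was 0.318. The genes with the smallest unadjusted p included Luc7l2, a factor associated with the U1 snRNP, at 70.1 ± 9.89 against 103 ± 4.65 TPM. Txnl4a, which encodes a U5 snRNP protein, averaged 14.7 ± 1.02 against 10.7 ± 0.14 TPM, and Acot1, an acyl-CoA thioesterase gene, 5.13 ± 0.805 against 8.57 ± 0.65 TPM. Dcun1d3 averaged 6.57 ± 0.422 against 4.2 ± 0.264 TPM, Fggy 8.82 ± 1.22 against 5.38 ± 0.506 TPM, Oscp1 1.39 ± 0.13 against 2.68 ± 0.201 TPM and Asprv1 0.61 ± 0.234 against 1.95 ± 0.21 TPM. The immunoglobulin segments Igkv4-53 and Igkv8-28 averaged 2.71 ± 0.48 against 0.493 ± 0.24 TPM and 0.307 ± 0.531 against 8.51 ± 7.76 TPM. At an unadjusted p under 0.05, 231 genes differed (115 higher, 116 lower) where 714 would by chance, and 777 (5.44%) had groups that did not overlap where chance gives 10%. The share that was higher, 49.8%, was 39.1% after median ratio scaling, 34.7% after quantile normalisation and 36.9% after rescaling. In all 9 of 52 lists passed, 7 higher and 2 lower, with 0 by an estimated correlation and 0 by fry; without vehicle library 2 there were 17 and without vehicle library 3 there were 16. Without vehicle 1, vehicle 2 or RECTAS 1 in turn, 1 gene passed.

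The RECTAS effect differed between tissues for 7 genes, tested as interactions in a fit of all 18 libraries over 17537 genes. Ddit4 had a larger effect in liver than in colon (difference 2.03, SE 0.32, adjusted p = 0.0446), where it averaged 25.3 ± 4.49 against 19.9 ± 3.69 TPM. This call was lost in 16 of 24 alternatives (adjusted p from 0.0206 to 0.123). Arrdc2, an arrestin-domain gene, averaged 28.8 ± 6.78 against 8.63 ± 0.692 TPM in liver and 13.5 ± 1.6 against 16.2 ± 2.14 TPM in colon (difference 1.85, adjusted p = 0.0127). The Arrdc2 call ended without colon vehicle 2 (0.0599), colon RECTAS 1 (0.0552) or liver RECTAS 3 (0.0643). Txnip, a thioredoxin-binding inhibitor of glucose uptake, was lower in liver and averaged 814 ± 56.6 against 730.2 ± 9.67 TPM in colon and 493 ± 65.2 against 431 ± 58.3 TPM in lung (liver minus colon −1.15, adjusted p = 0.0446; liver minus lung −1.20, adjusted p = 0.0459). The Txnip calls were lost in 17 and 18 of 24 alternatives (highest adjusted p = 0.129 and 0.127). The other 4 are predicted or uncharacterised transcripts. Rhob and Nr4a3, both immediate early genes, had lung minus colon differences of 1.15 and 1.26 that did not pass (adjusted p = 0.194 and 0.201). No gene was called in 2 tissues by the separate limma fits (0 for each pair, with 0, 1 and 2 calls to compare). The count of 7 rested on single libraries. It was 17 without lung vehicle 3, 15 without liver vehicle 1, 4 without colon vehicle 3, colon RECTAS 2, lung vehicle 1 or liver vehicle 3. It was 3 without colon vehicle 1, colon RECTAS 3 or lung vehicle 2, and 1 without colon vehicle 2, colon RECTAS 1 or liver RECTAS 3.

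Some genes passed as an average effect over the 3 tissues, and 14 of these 33 genes (5 higher, 9 lower) had groups that lay apart in every tissue. These results were added after the data had been seen, and so were the genes named here. Luc7l2 (ENSMUSG00000029823, chromosome 6, 38551334 to 38609470, plus strand) was lower in every tissue, at 70.1 ± 9.89 against 103 ± 4.65 TPM in colon (−32.0%), 119 ± 4.03 against 173 ± 9.63 TPM in lung (−30.9%) and 51.3 ± 3.39 against 86.3 ± 12.2 TPM in liver (−40.5%). Averaged over the tissues it fell by 0.61 on the log2 scale (SE 0.06, adjusted p = 0.000433 by limma), and it passed in 24 of 24 alternatives (adjusted p from 4.65e-05 to 0.00222). Alkbh3, a DNA and RNA demethylase gene (average −0.40), Mtcp1 (−0.44), Zc3h6 (−0.68) and Dnajc8, a spliceosome-associated J-domain protein gene (−0.24), also fell on average. Ddit4 (1.29), Tsc22d3 (1.18), Cdkn1a (0.59), Ccl25, a chemokine gene (0.50), Txnl4a (0.49), Herpud1, an endoplasmic reticulum stress gene (0.39), and the histone gene H2bc4 (0.36) rose on average. Adjusted p by limma ran from 0.000433 (Ddit4) to 0.047 (Txnl4a) for these genes. It ran from 0.00323 (Alkbh3) to 0.0162 (Dnajc8) for the former. Over the alternatives for the 33 genes, 526 kept the call and 257 lost it. The colon groups overlapped for Ddit4, Tsc22d3, Cdkn1a and Herpud1. The average effect passed for 33 of 17537 genes, 17 higher and 16 lower. Without single libraries the count was 14 (colon RECTAS 1), 16 (colon vehicle 3), 17 (lung vehicle 2 or liver RECTAS 3), 18 (lung RECTAS 3), 19 (lung vehicle 1), 20 (lung RECTAS 1), 21 (colon RECTAS 2) and 58 (liver vehicle 3).

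**Figure D4:**
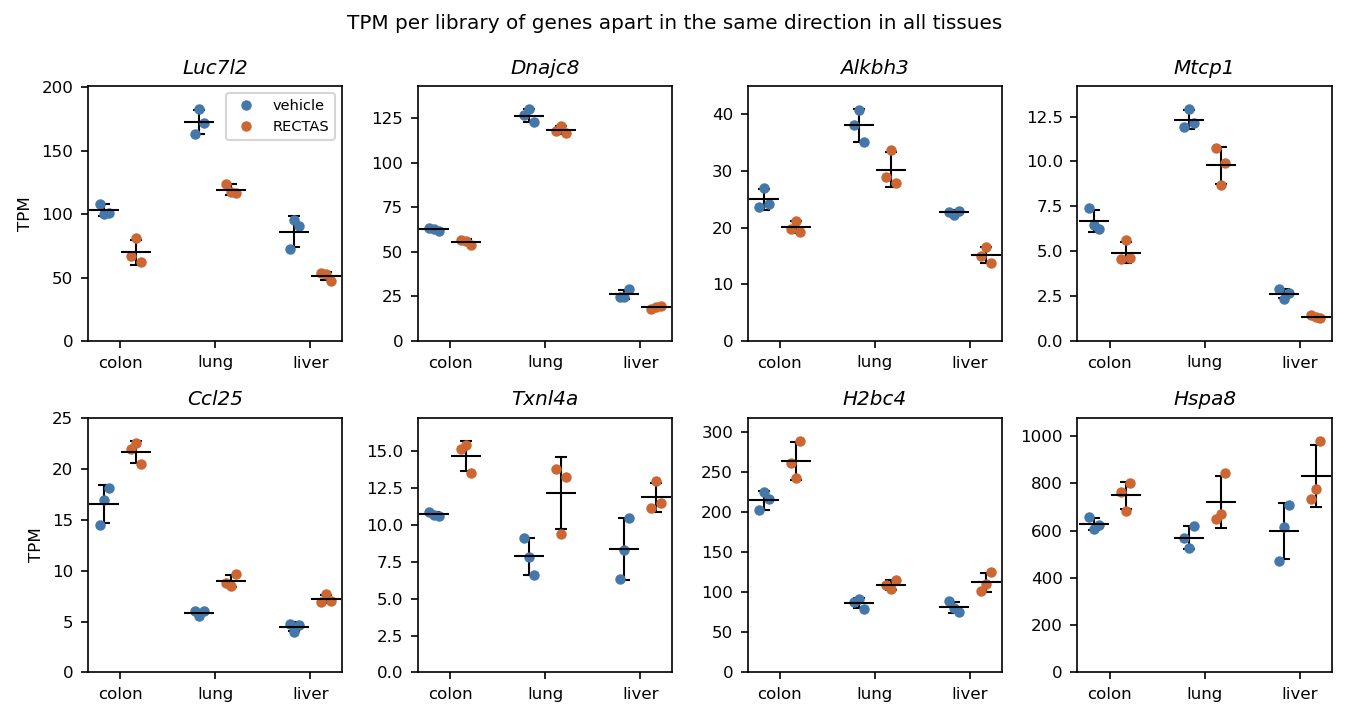
TPM of Luc7l2, Dnajc8, Alkbh3, Mtcp1, Ccl25, Txnl4a, H2bc4 and Hspa8 in each library (points) of colon, lung and liver, with the mean and SD of the 3 libraries per group. In each tissue the RECTAS libraries lie all on 1 side of the vehicle libraries for each gene, a property the genes were chosen for. Txnl4a, H2bc4 and Hspa8 lose this property after median ratio scaling.

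Counted without a model, 33 of 10753 genes expressed in every tissue had RECTAS libraries all above (22) or all below (11) the vehicle libraries in each of the 3 tissues. Relabelling the libraries within tissues gave as many genes in 24 of 8000 relabelings (exact p = 0.003 with the tissues taken as independent), with a mean of 2.62 and a highest other count of 88. The higher genes included the chaperone genes Hspa8 and Dnaja2, the kinase gene Sgk1 at 239 ± 92.8 against 119.7 ± 48 TPM in colon, the proteasome subunit genes Psmd7 and Psmd12, and Vcp, a segregase of ubiquitinated proteins. The lower genes included Luc7l2, Mtcp1, Alkbh3, Slc25a40, Sdr42e1 and Dnajc8. After median ratio scaling 31 genes met the criterion, 12 higher and 19 lower, and 14 genes were shared with the 33. Hspa8, Dnaja2, Psmd7, Psmd12, Vcp, Txnl4a, H2bc4 and Sdr42e1 were not among the 14. None of the fixed lists was enriched among the 33; the lowest adjusted p by Fisher's exact test was 0.11, for the glucocorticoid response list with 2 genes.

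**Figure D5:**
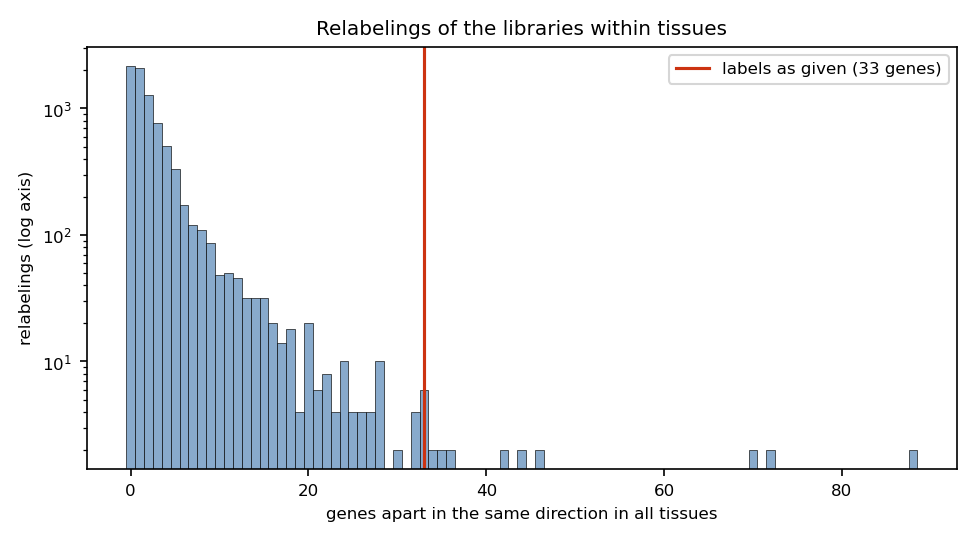
Number of the 8000 relabelings of libraries within tissues (log axis) by the count of genes whose groups lay apart in the same direction in all 3 tissues. The line marks the real count of 33, reached or passed in 24 relabelings.

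Splicing regulators were measured because RECTAS is a splicing modulator. Clk1, a kinase of SR proteins, averaged 151 ± 13.8 and 153 ± 13.5 TPM under vehicle and RECTAS in colon, 288 ± 10.1 and 303 ± 27.1 TPM in lung, and 56.4 ± 12.6 and 49.1 ± 4.68 TPM in liver. Srsf6, an SR protein gene, averaged 81.1 ± 7.02 and 80.0 ± 11.3 TPM in colon, 133 ± 4.77 and 133 ± 2.63 TPM in lung, and 48.4 ± 6.99 and 49.8 ± 1.35 TPM in liver. Clk2, Clk3 and Clk4 differed by −0.01, 0.22 and −0.11 in colon, 0.06, 0.13 and −0.03 in lung, and 0.01, 0.04 and −0.16 in liver. Cftr, the chloride channel gene, averaged 31.2 ± 2.1 against 33.6 ± 0.912 TPM in colon and 3.28 ± 0.559 against 2.52 ± 0.15 TPM in lung (adjusted p = 0.425), and lay below the filter in liver. None of these 6 genes passed in any tissue. Srsf5 was the highest SR protein gene, at 363 ± 26.1, 646 ± 51.3 and 272 ± 6.61 TPM under vehicle in colon, lung and liver.

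Of 36 core spliceosome genes, Luc7l2 alone fell adjusted over the list alone in each tissue (adjusted p = 0.049 in colon, 0.00233 in lung and 0.0158 in liver). Over all genes 0 of the 36 passed; Luc7l2 had adjusted p = 1 in colon, 0.145 in lung and 0.15 in liver. After median ratio scaling 2 members passed in liver. The lung call held without each library in turn. The colon call ended without vehicle 1 (0.202), vehicle 2 (0.153), vehicle 3 (0.185), RECTAS 1 (0.231) or RECTAS 3 (0.141), and the liver call without vehicle 2 (0.0724), vehicle 3 (0.0606), RECTAS 1 (0.0663), RECTAS 2 (0.0737) or RECTAS 3 (0.0895). The core spliceosome list as a group gave adjusted p = 0.897, 1 and 0.892 by camera in colon, lung and liver. The CLK, DYRK and SRPK kinase list gave 0.696, 0.999 and 0.842, SR protein genes 0.681, 0.864 and 0.849, nonsense-mediated decay genes 0.541, 0.809 and 0.892, and hnRNP genes 0.541 in colon and 0.0584 in liver.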

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

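Tests of libraries split at the level of genes, all tests of Luc7l2, of genes apart in all 3 tissues and of the averaged effect, and those of vehicle libraries numbered 1, of the time of day and of RECTAS acting on hepatocyte genes were chosen only after the result was seen; the other tests in this part were set beforehand.

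The RECTAS effect differed between tissues, by limma's interaction test, in 11 comparisons of 7 genes. Ddit4 (liver minus colon 2.03), Arrdc2 (liver minus colon 1.85) and Txnip (liver minus colon −1.15, liver minus lung −1.20) are expressed in all 3 tissues. Gm43198 differed between lung and colon by 3.34, at 5.65 ± 1.18 against 0.433 ± 0.7505 TPM in lung and 0.05 ± 0.0866 against 1.17 ± 0.528 TPM in colon. The transcript 4632432E15Rik differed by 0.84 (lung minus colon) and −0.85 (liver minus lung), Gm45724 by −1.66 (liver minus colon) and −1.59 (liver minus lung), and Gm32511 by −1.11 and −1.10. These last 3 lay near 0 TPM in the other tissues, and the fit shares 1 estimate of the spread over the tissues. Of 100 regroupings of libraries within tissues, the real one included, 38 called at least 7 genes and the highest other called 668, so chance could not be excluded for the count.

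Luc7l2 was lower in all 3 tissues, and 33 genes lay apart in the same direction in all 3. Chance agreement between independent tissues is argued against by the exact share of 0.003 of relabelings with as many genes. If same-numbered libraries of the 3 tissues came from 1 animal, 10 splits exist, too few for a share under 0.05. Of these 1 gave as many (highest other 5), which holds only for this matching of the numbers. Library scaling is argued against for Luc7l2, whose average difference stayed at −0.61 after median ratio scaling, and for the size of the count, which was 31. It is not for most of the genes: 14 of the 33 still met the criterion, and 22 higher and 11 lower genes became 12 and 19. Reads moved to the paralogs Luc7l and Luc7l3 are argued against as the main source: in TPM times exon length their net change was 0.836% of the Luc7l2 loss in lung, −0.0062% in colon and −6.07% in liver, and Luc7l alone gained 2.45%, 2.62% and 3.09%. A response to RECTAS shared by the tissues may account for Luc7l2 as a hypothesis; if the tissues came from the same animals, differences between animals stay open.

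Glucocorticoid response genes were higher in liver and lung. The vehicle libraries numbered 1 are argued against as the whole source, since without them the list median kept 69.9% of its value in liver and 82.0% in lung. A different time of day in the arms stays open: a clock index moved by −0.24 in liver, −0.20 in lung and 0.12 in colon with overlapping arms (exact permutation p = 0.4, 0.4 and 0.9), and 3 against 3 libraries cannot give less than 0.1. Both arms were dosed by mouth at the same interval, so handling common to both would not by itself separate them. A glucocorticoid or handling response that differed between the arms, or an action of RECTAS, may each account for it. Neither was tested apart from the other.

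Hepatocyte genes were lower in lung under RECTAS. Liver RNA in the lung libraries, from carry-over at dissection for example, could account for it and stays open. Across liver genes outside the list, the difference between lung vehicle library 3 and lung RECTAS library 1 followed liver TPM with a Spearman rho of 0.80 across genes, which are not independent replicates. That value was at, not over, the bound of 0.8 set beforehand, so the test did not decide. All 56 of these genes were higher in vehicle library 3, by a median of 1.65% of their liver TPM (quartiles 1.39% to 1.86%). A looser criterion that counted this even share in favour of liver RNA was tried after these values were seen and was dropped. RECTAS lowering these genes in lung is argued against as the whole source. The centred median of the hepatocyte list ran from −1.93 to 2.93 within the vehicle libraries and from −2.75 to 1.60 within the RECTAS libraries. Libraries of 1 arm had the same treatment, so RECTAS cannot account for these spans. By this median a RECTAS library lay above a vehicle library in 3 of 9 pairs. A smaller lowering by RECTAS beside another source stays open.

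Over splits of the 6 libraries of a tissue, 10 exist, too few for a share under 0.05. In colon the real count was 0 genes, which 10 of 10 splits reach by definition, so it tests nothing (highest other 13); 9 of 10 called at least the real 9 lists (highest other 27). In lung 6 of 10 called at least the real 1 gene (highest other 69) and 5 of 10 at least the real 21 lists (highest other 24). In liver 2 of 10 called at least the real 2 genes (highest other 2) and 3 of 10 at least the real 17 lists (highest other 23). The count of 69 in lung, many times the real one, points to a structure of the samples; that split set vehicle 1, RECTAS 1 and RECTAS 2 against the rest and followed the hepatocyte RNA. Of 100 regroupings within tissues 19 called at least the 33 genes of the averaged effect (highest other 130), so chance could not be excluded for that count.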

How the results depend on the processing

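Leaving out libraries, scalings and model settings were planned; fits without genes under 300 nt, fits of genes expressed in every tissue, and all tests of the averaged effect were chosen only after the result was seen. Depth is unknown for TPM, so its limit on low genes could not be measured. Of 3880 alternatives for named genes in 1 tissue, 3811 kept direction and side of the threshold, 9 lost a call, 33 gained one and 27 reversed. In 1411 of them the filter, variance or threshold was changed, or the fit extended. There the difference itself could not move, so they bear on calls alone. Only a called gene can lose a call. Ddit4 in liver lost it in 6 of 19 alternatives, Gm44313 in liver in 2 of 18 and Gm25791 in lung in 1 of 18. Most of the 3811 were genes that did not pass and stayed so. For tissue differences 105 kept and 152 lost a call. For lists, whose direction is that given by camera, 362 kept, 168 lost and 6 reversed, while the list median changed sign in 16 cases. For genes averaged over tissues 526 kept and 257 lost. The cause was not tested for any of the values below.

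Lists passed in 0 cases with an estimated correlation in colon, lung, liver and averaged; by fry 0, 2, 1 and 1 passed. Colon genes changed were 2 with a pseudocount of 0.1 and 1 in the fit of all 18 libraries. Lung genes changed were 33 (31 higher, 2 lower) in that fit, 4 with array weights, 2 at a threshold of 0.1 and 0 without genes under 300 nt. Liver genes changed were 94 (43 higher, 51 lower) in that fit, 62 (33 and 29) with array weights, 7 with a filter of 5 TPM, 5 with quantile normalisation, 5 with median ratio scaling, 8 when rescaled without mitochondrial and top 20 genes, 6 with robust variance, 8 at a threshold of 0.1 and 1 without genes under 300 nt. Tissue differences were 2 with a pseudocount of 0.1, 43 with no filter and 4 among genes expressed in every tissue. The averaged effect called 171 genes (118 and 53) with array weights.

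Signs of small differences turned: Clk1 in colon with quantile normalisation (−0.033) and rescaling (−0.016), and in lung with quantile normalisation (−0.055); Srsf6 in colon with array weights (0.0048); Clk2 in colon (0.012) and liver (−0.041) with array weights and in lung with quantile normalisation (−0.023) and rescaling (−0.00083).

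Without single libraries, colon genes changed ranged from 0 to 1, lung from 1 to 2 and liver from 1 to 6, colon lists from 8 to 17, tissue differences from 1 to 17 and the averaged effect from 14 to 58. List medians ranged from −0.33 to 0.088 (cell cycle, colon), −0.19 to 0.11 (cell cycle, lung), −0.069 to 0.29 (fatty acid synthesis, liver) and −0.26 to 0.025 (interferon gamma, colon). The NRF2 median in colon ranged from 0.0201 to 0.14, and its camera direction turned. Medians that changed sign also ranged from −0.054 to 0.25 (PPARA, liver), −0.060 to 0.18 (unfolded protein, liver), −0.024 to 0.23 (cell cycle, liver), −0.12 to 0.097 (club cell, lung), −0.25 to 0.0086 (B and plasma cell, lung) and −0.40 to 0.013 (erythroid, lung). Clk1 ranged from −0.065 to 0.082 in colon, Clk2 from −0.079 to 0.10 in colon, −0.028 to 0.16 in lung and −0.041 to 0.082 in liver, and Clk3 from −0.024 to 0.12 in liver. Srsf6 ranged from −0.10 to 0.094 in colon, −0.028 to 0.023 in lung and −0.052 to 0.15 in liver.

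With the replicate number as a block, 0 genes and 12 lists passed in colon, 1 and 23 in lung, 0 and 18 in liver, with 6 tissue differences and 34 averaged genes. Whether the numbers pair the samples was not settled. Within tissues 3 of 9 correlations of same-numbered libraries were above 0.1 (−0.294 to 0.409), and 3 libraries correlated best with their own number. Across tissues 0 of 18 were above 0.1 (−0.0601 to 0.065), and 8 correlated best with their own number.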

Other observations

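The tests of annotated decay transcripts, of changes in either direction and of lists averaged over the tissues were chosen only after the result was seen, and the test of single-exon genes was set beforehand.

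In liver, genes for pre-mRNA binding proteins passed no test of a shift in 1 direction. Of 26 hnRNP genes 21 were lower (adjusted p = 0.498 by fry, 0.0584 by camera and 0.802 with an estimated correlation), with Hnrnpu at 63.6 ± 3.84 against 82 ± 14.8 TPM, Hnrnpa1 at 60.4 ± 2.86 against 72 ± 7.56 TPM and Pcbp2 at 226 ± 11 against 249.7 ± 9.09 TPM. Among core spliceosome genes, Luc7l3 stood at 17.3 ± 1.03 against 22.6 ± 1.85 TPM, Snrnp200, the U5 helicase gene, at 17.3 ± 0.96 against 20.8 ± 1.12 TPM and Prpf8 at 35.9 ± 1.96 against 41 ± 0.618 TPM. Sf3b4, an SF3b subunit gene of the U2 snRNP, stood at 13.9 ± 0.254 against 10.8 ± 1.07 TPM. None of these 7 genes was past the threshold in liver over all genes or over its list alone. As changes in either direction, fry gave adjusted p = 0.0108 for the hnRNP list and 0.00799 for the core spliceosome list in liver, 0.0365 and 0.0414 in lung, and passed for 9 of 47 lists in liver, 14 of 55 in lung and 0 of 52 in colon. This test was read after the camera results and does not compare a list with other genes. By camera the hnRNP list ranked higher in lung (adjusted p = 0.0243; 0.786 with an estimated correlation and 0.269 after median ratio scaling); the difference between the tissues was not tested.

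Averaged over the tissues, 13 of the lists passed camera, 7 higher and 6 lower, with 0 by an estimated correlation and 1, the glucocorticoid response, by fry (adjusted p = 0.0064). Heat shock genes had a median average difference of 0.22 and 12 members that passed adjusted over the list alone, counted in either direction (camera adjusted p = 1.08e-12; adjusted p = 0.426 with an estimated correlation). Cholesterol synthesis genes had a median of 0.21 with 0 such members (7.4e-08; adjusted p = 0.834 with an estimated correlation), and interferon gamma genes a median of −0.20 with 0 such members (3.37e-06; adjusted p = 0.834 with an estimated correlation).

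As hypotheses on splicing, single-exon genes could shift relative to spliced genes, and genes with annotated decay transcripts could be frequent among those lowered. The difference between 153 single-exon and 9931 spliced genes, averaged over tissues, gave an exact permutation p of 0.911 over 8000 relabelings. The bound set beforehand, a p of 0.05 or more, was too weak to exclude a shift, since a p that misses the threshold does not show equal values. Of 9 coding genes lowered on average 3 had an annotated decay transcript, against 26.8% of 14899 others (Fisher's exact p = 0.709, two-sided), too few genes to decide.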
